A study of Mus musculus with 43 samples.

How the data were processed

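RNA of sorted CD4 T cells was hybridized to 43 single-colour arrays, 1 sample per array. Per the labels' protocols, cells were sorted as CD4, CD90.2 and CD45.1 positive into Trizol, RNA of 0.1 to 30 ng with an integrity number above 8 was amplified with the Ovation Pico WTA V2 kit, and the cDNA was labelled with the Encore Biotin kit. The values deposited by the authors were used as deposited, as log2 signal of each probe set, given to 2 decimals. The log base was judged from the values, which ran from 1.46 to 13.87; the background, summarization and normalization methods are not given in the sources used here. Array medians lay within 3.28 to 3.44. Since amplification from little RNA and the floor of the scale compress low signals, fold changes of dim genes can be too small.

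Of 41345 probe sets, 23521 carried 1 gene symbol, 1814 several and 16010 none; only those with 1 symbol were tested. Where a symbol had more than 1 probe set, as 1082 did, the probe set with the highest mean over all arrays was kept, which left 22180 genes. Symbols were compared with a RefSeq gene table, which held 23328 of the 23521 names; the other 193 were kept under the name given. No intensity filter was used. Genes without a usable probe set, Tcf7 and Rag1 of the genes fixed by name and some members of the gene lists among them, were not analysed here.

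All arrays entered a single linear model of limma 3.58.1 in R 4.3.3, with a mean for each of 9 groups (lmFit, then eBayes with a trend of the prior variance on the mean level). Each of 12 differences between groups and 2 interactions, the effect of int or of low antigen on day 30 minus that on day 10, was tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 22180 genes. Counts of calls with at least a 2-fold change stand beside. The direction of a value that was not called is not read. Groups had 4 or 5 arrays. On planted changes, the test of int against none on day 10, run on simulated data with 50 genes at each size, recovered 16% at log2 0.5, 80% at 1, 94% at 1.5 and 100% at 2, with 10 false calls (6.452% of calls); weaker changes than these can therefore be missed.

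A total of 20 gene lists with 462 members, 413 of them measured, were fixed before the data were examined. They cover TCR-induced early, anergy-associated, Th1, Tfh, Th2 and Th17, Treg and Tr1, cytotoxic, naive and central memory, cell cycle, glycolysis and nutrient uptake, oxidative phosphorylation, interferon-stimulated and apoptosis genes, inhibitory receptors, exhaustion-associated transcription factors, chemokine and homing receptors, and markers of B, myeloid, erythroid and NK, CD8 or gamma-delta T cells. Each list was tested in each comparison with camera from limma at the preset correlation between genes of 0.01, adjusted over the 20 lists, and again with a correlation estimated from the residuals. Of 280 such tests 123 had an adjusted p under 0.05, and 64 of these kept it with an estimated correlation. Members were also counted with p-values adjusted over the list alone. On simulated data camera called a planted list and 1 other list. A wrong match of 1 symbol of the glycolysis list to another gene was corrected after results had been seen.

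The comparisons, the lists, the main test, the rule for named genes and all alternatives but those named as chosen later were fixed before the data were examined. Egr2, Nr4a1, Pdcd1, Lag3, Tox, Il7r, Ifng, Tbx21, Il2, Foxp3, Bcl6 and Mki67 were fixed for every antigen comparison whatever their values. The other names came from up to 8 called genes with the highest and 8 with the lowest fold change, leaving out unnamed genes, immunoglobulin and receptor segments, small RNAs and histones, from up to 4 members of a list with the largest change, and from the 8 genes with the largest off change among those called in both int and off against none on day 30. Cd4, Cd3e, Thy1, Ptprc, Rag2 and Xist were fixed as sample checks. From the genes that these rules allow, those whose call held on leaving out each array in turn were preferred as examples, a choice made after the values were seen; of 496 calls of named genes, 382 held in this way and 114 did not. Genes used in weighing explanations were chosen after the values were seen.

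Agreement between comparisons was described with Pearson and Spearman correlations over all genes. For comparisons that share controls it was set beside 100 simulations of unchanged groups against the same number of controls and beside a division of the none arrays between the comparisons. The share of the int effect left in off is the least squares slope through the origin of off minus none on int minus none. The 5 none arrays were divided 2 and 3 in all 20 ordered ways. A planted share of 0.4 gave 0.3896 in simulation on the planted genes. Each comparison was also repeated on up to 100 other divisions of the same arrays into groups. Arrays far from their group were found with Dixon's gap test at its 95% level.

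Alternatives were a block for the replicate number, a filter on dim genes, quantile normalization, centring of each array on its median, a fit of only the groups compared, array quality weights, eBayes without a trend, the mean of all probe sets of a gene, and leaving out each array in turn. After the data had been seen, leaving out 4 arrays together (naive replicates 3 and 4, day 10 high replicate 2 and day 10 none replicate 4) and taking each off array on its own were added. The last pair had the lowest quality weights among the day 10 arrays; day 30 low replicate 4, with a weight between theirs, was kept. The tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and the figures were drawn with matplotlib 3.10.9.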

Results

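Expression was measured on 43 single-colour arrays of mouse CD4 T cells that had been transferred into recipient mice and sorted back out. The donor cells carried the AND receptor, a transgenic T cell receptor that sees a peptide of moth cytochrome c, lacked Rag2 and bore the CD45.1 marker by which they were sorted. In the iMCC recipients the peptide is made by dendritic cells while doxycycline is in the drinking water, so that the drug sets when and how strongly the T cells meet antigen. Every iMCC recipient drank 100 µg/ml at the time of transfer. From day 3 the none group received no doxycycline, the low group 10 µg/ml and the intermediate (int) group 100 µg/ml. The off group followed the int schedule to day 10 and was then taken off the drug. A high group came from cMCC mice, another recipient strain in which MHC class II positive cells make the peptide constitutively and which received no doxycycline, and naive AND cells were sorted 3 days after transfer into mice without either transgene.

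On day 10 the none and low groups had 5 arrays each and the int and high groups 4 each. On day 30 the none, low, int and off groups had 5 arrays each, and the naive group had 5. The day 30 cells came from a later series of sorts, so day and sort series cannot be told apart. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may in part be technical. The number of arrays limits the precision of every value. Array medians lay between 3.28 and 3.44 on the log2 scale. Transcripts of the sort markers were high in every group, with group means of 9.12 to 10.0 for Cd4, 10.12 to 11.20 for Thy1 (CD90) and 10.96 to 11.30 for Ptprc (CD45), while Rag2 lay at 2.59 to 3.04. Values for single genes are log2 fold changes ± SE with limma's adjusted p, and levels are log2 means ± SD. Unless a sentence says otherwise, each array of the first group lay beyond all arrays of the second for every called gene that is named. Gene lists were tested with camera, and a call of a list held with an estimated correlation between genes unless a second p is given.

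Cells primed by antigen until day 3 and left without it were first compared with naive cells. Besides priming, the naive cells differ in time after transfer (day 3 against day 10 or 30), in recipient genotype and in having had no doxycycline. What brief priming leaves behind cannot be told apart from these differences. The labels describe cells primed briefly in this way as developing into Th1 memory cells. On day 10 the none group had far more of the transcripts that mark Th1 effectors. Ccl5, a chemokine of effector and memory T cells, was higher (log2 fold change 5.15 ± 0.52 SE, adjusted p = 1.21e-09). So were Cxcr3, the chemokine receptor of Th1 cells (4.31 ± 0.19, adjusted p = 3.24e-21), and Tbx21, which encodes the Th1 master regulator T-bet (2.58 ± 0.24, adjusted p = 7.38e-11). Il7r, the receptor chain through which memory T cells receive IL-7, stood at 10.25 ± 0.33 (SD, n = 5) against 7.52 ± 0.91 in naive cells (2.73 ± 0.42, adjusted p = 1.33e-05). Lower than in naive cells were Nr4a1, an immediate early gene of T cell receptor signalling (-2.90 ± 0.28, adjusted p = 3.21e-10), and Tnfrsf9, the costimulatory receptor 4-1BB (-3.26 ± 0.41, adjusted p = 2.8e-07). The Treg factors Ikzf2, which encodes Helios (-3.26 ± 0.38, adjusted p = 4.28e-08), and Foxp3 (-1.55 ± 0.26, adjusted p = 6.02e-05) were lower as well. Naive levels of some of these genes were as high as under antigen. Nr4a1 stood at 8.46 ± 0.29 in naive and 8.35 ± 0.51 in day 10 int cells, Ikzf2 at 8.98 ± 0.31 and 8.49 ± 0.33, and Mki67 at 5.23 ± 0.78 and 4.65 ± 0.68. Lag3 did not follow (5.16 ± 0.40 and 9.21 ± 0.31). A fall against naive cells is therefore not by itself a loss through priming. In all, limma called 733 genes, 421 higher and 312 lower in the none group, 288 of them by at least 2-fold.

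Among the 23 measured Th1 genes, 11 were higher, 0 lower and 12 not called (13 and 0 adjusted over the list alone, camera adjusted p = 4.95e-32). Cytotoxic genes went the same way: of 17, 4 were higher, 0 lower and 13 not called (8 and 1 adjusted over the list alone, camera adjusted p = 1.7e-07). Nkg7 was at 3.27 ± 0.27 and Klrd1 at 1.75 ± 0.41. Chemokine and homing receptors rose as a list (camera adjusted p = 1.75e-06), with 9 and 3 adjusted over the list alone. Itgb1 (3.5 ± 0.20) and Itga4 (2.61 ± 0.15), the chains of the integrin VLA-4, were higher and Ccr8 (-2.72 ± 0.28) lower. Of 42 cell cycle genes, 0 were higher, 14 lower and 28 not called (0 and 21 adjusted over the list alone, camera adjusted p = 1.16e-18). Nusap1 (-1.65 ± 0.27, adjusted p = 3.46e-05) and Ccna2 (-1.6 ± 0.25, adjusted p = 2.72e-05) were among them. TCR-induced early genes fell too, with 7 of 28 lower and 1 higher (5 and 14 adjusted over the list alone, camera adjusted p = 8.9e-06). Of 22 naive and central memory genes, 3 were higher, 8 lower and 11 not called (4 and 10 adjusted over the list alone). By camera the list was lower (adjusted p = 0.00165), though not at adjusted p = 0.174 with an estimated correlation. Igfbp4 (-2.54 ± 0.21) fell, while Klf2, which drives the exit receptors of resting T cells, rose (1.26 ± 0.20).

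Several further lists passed camera only with the preset correlation. Interferon-stimulated genes were higher (adjusted p = 1.02e-06, and adjusted p = 0.0506 with an estimated correlation), with 4 of 28 called and 12 and 0 adjusted over the list alone. Inhibitory receptors (adjusted p = 0.0145, and 0.101 with an estimated correlation), exhaustion-associated transcription factors (0.0384 and 0.359), Treg and Tr1 genes (0.0165 and 0.171) and oxidative phosphorylation genes (0.000527 and 0.181) were lower. Adjusted over the list alone, 2 inhibitory receptors were higher and 6 lower, 3 exhaustion factors higher and 6 lower, 2 Treg and Tr1 genes higher and 7 lower, and 0 oxidative phosphorylation genes either way. Maf, a transcription factor on the exhaustion, Tfh and Treg lists, went against their direction (5.15 ± 0.46, adjusted p = 3.91e-11). Anergy-associated genes (7 higher and 5 lower, adjusted p = 0.876), Tfh genes (2 and 4, 0.876), Th2 and Th17 genes (0 and 1, 0.235), glycolysis genes (4 and 0, 0.235) and apoptosis genes (0 and 1, 0.876) were not called as lists.

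Markers of other cell types differed in this comparison as well. Of 14 B cell and plasma cell markers, 0 were higher, 4 lower and 10 not called (0 and 5 adjusted over the list alone, camera adjusted p = 2.73e-05). Cd79a was at -2.12 ± 0.36, adjusted p = 7.92e-05, with 4 of 5 arrays beyond all naive ones. Myeloid and dendritic cell markers were lower with the preset correlation (adjusted p = 0.000198, and adjusted p = 0.0636 with an estimated correlation). Of 25 members 2 were called (0 and 3 adjusted over the list alone), H2-Ab1 at -2.01 ± 0.28, adjusted p = 1.62e-06. Erythroid and platelet markers (0 of 7 called, adjusted p = 0.51) and NK, CD8 and gamma-delta T cell markers (0 of 8, adjusted p = 0.876) were not. Naive replicates 3 and 4 carried most of this signal, with Cd79a at 7.68 and 6.65 against 3.95 to 5.0 in the other naive arrays, Lyz2 at 8.34 and 7.39 against 2.61 to 3.47, and S100a8 at 10.7 and 10.18 against 5.11 to 7.72. Without those 2 arrays, a setting chosen after seeing the data, 337 genes were called, 318 of them among the 733. Foxp3 (-1.55 ± 0.26 with all arrays) was at -1.26 (adjusted p = 0.00424) and Mki67 at -1.11 (adjusted p = 0.0301). Leaving out day 10 none replicate 4 and day 10 high replicate 2 as well gave 384 calls. The calls of Pdcd1 (-1.48 ± 0.33, adjusted p = 0.00392 with all arrays) and Mki67 (-1.61 ± 0.28, adjusted p = 0.000129 with all arrays) ended (adjusted p = 0.184 and 0.0605).

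By day 30 the none group differed from naive cells in 961 genes, 439 higher and 522 lower. Ccl5 (5.25 ± 0.52, adjusted p = 7.77e-10), Cxcr3 (4.07 ± 0.19, adjusted p = 2.88e-20), Tbx21 (2.03 ± 0.24, adjusted p = 5.1e-08) and Ifng, the Th1 cytokine interferon gamma (1.62 ± 0.34, adjusted p = 0.00191), were higher. Il7r stayed above the naive level (2.77 ± 0.42, adjusted p = 1.26e-05). Top2a (-1.79 ± 0.20, adjusted p = 1.56e-08) and Mki67 (-1.85 ± 0.28, adjusted p = 1.5e-05), both of dividing cells, were lower. So were Nr4a1 (-2.33 ± 0.28, adjusted p = 9.26e-08) and Tox, a transcription factor of chronically stimulated T cells (-1.22 ± 0.20, adjusted p = 7.34e-05). Th1 genes had 12 of 23 members higher and 0 lower (15 and 0 adjusted over the list alone, camera adjusted p = 6.17e-21). Cell cycle genes fell as a list (0 higher and 16 lower of 42, 0 and 27 adjusted over the list alone, camera adjusted p = 2.44e-25). TCR-induced early genes did so too (0 higher and 7 lower of 28, 0 and 9 adjusted over the list alone, camera adjusted p = 6.05e-08), as did naive and central memory genes (2 higher and 11 lower of 22, 3 and 13 adjusted over the list alone, camera adjusted p = 6.56e-08). Cytotoxic genes rose (4 higher and 1 lower of 17, 7 and 1 adjusted over the list alone, camera adjusted p = 9.64e-05). For the chemokine and homing receptors the median was -0.02 and the mean 0.32, and the upward call (adjusted p = 0.0237) was lost (adjusted p = 0.0716 with an estimated correlation). Interferon-stimulated genes (adjusted p = 9.64e-05, and 0.0961 with an estimated correlation) were higher and inhibitory receptors (0.00898 and 0.0771), exhaustion-associated transcription factors (0.00351 and 0.182) and Treg and Tr1 genes (0.00369 and 0.0794) lower only with the preset correlation. The markers of B cells (camera adjusted p = 0.00049) and of myeloid cells (camera adjusted p = 1.81e-05) were again lower than in the naive group, the largest of these differences being S100a8 (-4.56 ± 0.79, adjusted p = 0.000148). Without naive replicates 3 and 4, 594 genes were called, 496 of them among the 961.

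**Figure D1:**
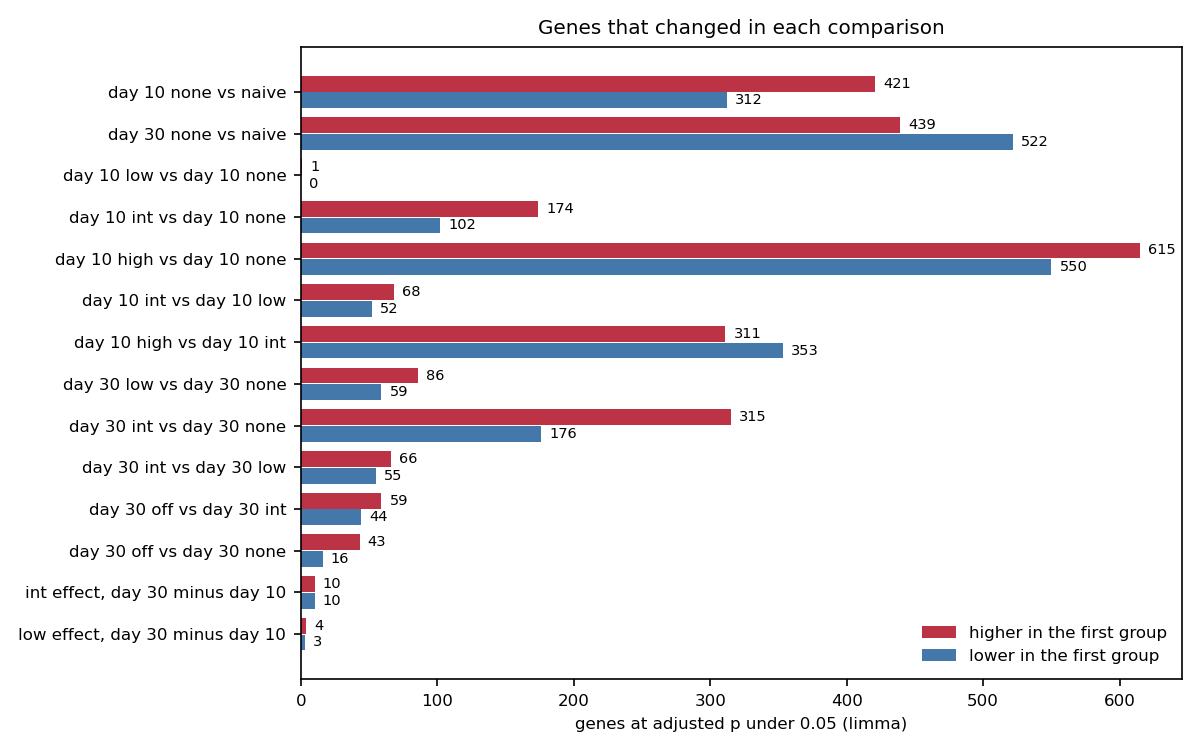
Number of genes called higher (red bars) and lower (blue bars) by limma in each of the 14 comparisons, on a linear axis that starts at 0. High antigen against none on day 10 gave the most calls, 615 and 550, and low antigen against none on day 10 gave 1 and 0.

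The next comparisons set each dose of persisting antigen against the none group of the same day, which asks what continued antigen does to cells primed in the same way. On day 10 few single genes were called for low antigen, and their number depended on the setting. limma called 1 gene, Smc4, a condensin subunit of dividing cells, which was higher in low (0.52 ± 0.09, adjusted p = 0.0382, 4 of 5 arrays beyond all none arrays). The call ended on leaving out any 1 of low replicates 1 to 4 or none replicates 1, 4 and 5 (adjusted p 0.086 to 0.399). It also ended with quantile normalization (0.6), with centring (0.0511), without a variance trend (0.245), with only these groups in the fit (0.473) and without 4 arrays (0.258). With array quality weights the count rose to 13, 8 higher and 5 lower, and with only these groups in the fit it was 2. At an unadjusted p under 0.05 there were 760 of 22180 genes, a share below the 0.05 expected where nothing changes. Of the genes fixed for every antigen comparison, Lag3 stood at 5.71 ± 0.45 in low and 5.09 ± 0.51 in none. Pdcd1 stood at 5.62 ± 0.26 and 4.89 ± 0.33, and Bcl6 at 6.79 ± 0.27 and 5.75 ± 0.45. None of these 3 was called (Bcl6 1.04 ± 0.27, adjusted p = 0.619), nor were Egr2, Nr4a1, Tox, Il7r, Ifng, Tbx21, Il2, Foxp3 or Mki67. camera called 7 lists higher with the preset correlation and 0 with an estimated one. These were exhaustion-associated transcription factors (adjusted p = 0.000221, and 0.302 with an estimated correlation), oxidative phosphorylation genes (0.000221 and 0.302), inhibitory receptors (0.00354 and 0.208), anergy-associated genes (0.00455 and 0.302), Tfh genes (0.00709 and 0.302), TCR-induced early genes (0.00934 and 0.302) and interferon-stimulated genes (0.0462 and 0.467). Not a single member of any list was called over all genes, and adjusted over the list alone at most 2 members of a list were, both higher among the exhaustion factors and 1 higher and 1 lower among the cell cycle genes.

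Intermediate antigen changed 276 genes on day 10, 174 higher and 102 lower, 170 of them by at least 2-fold. Lag3, an inhibitory receptor that binds MHC class II, rose from 5.09 ± 0.51 to 9.21 ± 0.31 (4.12 ± 0.45, adjusted p = 6.43e-08). Tnfsf4, the OX40 ligand, rose most (4.91 ± 0.54, adjusted p = 6.43e-08). Nr4a1 (2.79 ± 0.29, adjusted p = 6.43e-08) and Irf4, a transcription factor induced in proportion to receptor signal (2.82 ± 0.30, adjusted p = 6.43e-08), rose. So did Eomes, the T-box factor related to T-bet (3.15 ± 0.51, adjusted p = 8.3e-05). Of the cytokines, Il21 (3.16 ± 0.44, adjusted p = 6.9e-06), Ifng (2.22 ± 0.36, adjusted p = 8.73e-05) and Il10 (2.35 ± 0.42, adjusted p = 0.000516) rose. Il7r fell from 10.25 ± 0.33 to 6.25 ± 1.29 (-4.00 ± 0.44, adjusted p = 6.73e-08). Il18r1, a chain of the IL-18 receptor (-2.93 ± 0.36, adjusted p = 5.85e-07), and Gpr183, a guidance receptor for oxysterols (-1.55 ± 0.22, adjusted p = 8.92e-06), fell as well. The stress-induced chaperone Hspa1b was also lower (-3.46 ± 0.73, adjusted p = 0.00465).

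TCR-induced early genes rose as a list (10 higher and 3 lower of 28, 17 and 4 adjusted over the list alone, camera adjusted p = 1.68e-13), Egr2 by 1.82 ± 0.31, adjusted p = 0.000191. Jun (-2.89 ± 0.54, adjusted p = 0.000892), part of the AP-1 factor, went the other way. Exhaustion-associated transcription factors rose (6 higher and 0 lower of 15, 10 and 0 adjusted over the list alone, camera adjusted p = 1.28e-23), Tox by 1.08 ± 0.21, adjusted p = 0.00196. Inhibitory receptors had 5 of 17 members higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 2.11e-08). Tigit (3.07 ± 0.42, adjusted p = 5.48e-06) and Ctla4 (1.32 ± 0.24, adjusted p = 0.000625) were among them. The fifth, Pdcd1, which encodes PD-1, was called at 1.31 ± 0.35, adjusted p = 0.0429. That call ended on leaving out int replicate 1, 3 or 4 or any single none array (adjusted p 0.0528 to 0.282). Anergy-associated genes rose too (8 higher and 2 lower of 24, 12 and 3 adjusted over the list alone, camera adjusted p = 2.91e-12). So did Treg and Tr1 genes (7 higher and 0 lower of 20, 11 and 0 adjusted over the list alone, camera adjusted p = 4.72e-10). The third list to rise with them was that of Tfh genes (7 higher and 2 lower of 18, 11 and 2 adjusted over the list alone, camera adjusted p = 1.12e-10). Bcl6, the master regulator of follicular helper cells (2.46 ± 0.29, adjusted p = 2.54e-07), and its partner receptor Cxcr5 (1.63 ± 0.26, adjusted p = 6.86e-05) were higher. Cell cycle genes rose as a list with only 2 of 42 called (5 and 0 adjusted over the list alone, camera adjusted p = 0.000115), Top2a at 1.09 ± 0.21, adjusted p = 0.00135. Mki67 was not called (1.04 ± 0.30, adjusted p = 0.0737), except on leaving out int replicate 1 (adjusted p = 0.0483) or with array quality weights (0.0108).

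Th1 genes did not shift as a list under intermediate antigen (3 higher and 3 lower of 23, 5 and 4 adjusted over the list alone, camera adjusted p = 0.99). Tbx21 (0.24 ± 0.25, adjusted p = 0.934), Il2 (-0.15 ± 0.47, adjusted p = 0.999) and Foxp3 (-0.21 ± 0.27, adjusted p = 0.967) were not called. Naive and central memory genes (adjusted p = 0.0314, and 0.434 with an estimated correlation) and interferon-stimulated genes (1.63e-05 and 0.0914) were lower only with the preset correlation. Of their members 5 and 1 were called lower and 0 higher. Adjusted over the list alone, 6 were lower and 2 higher in the former and 1 lower in the latter. Of the interferon-stimulated genes, Oas2 fell (-2.35 ± 0.31, adjusted p = 2.58e-06). The remaining 10 lists, those of other cell types included, were not called (camera adjusted p 0.221 to 0.99). The count of calls dropped to 171 without int replicate 3 and to 170 without int replicate 4.

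**Figure D2:**
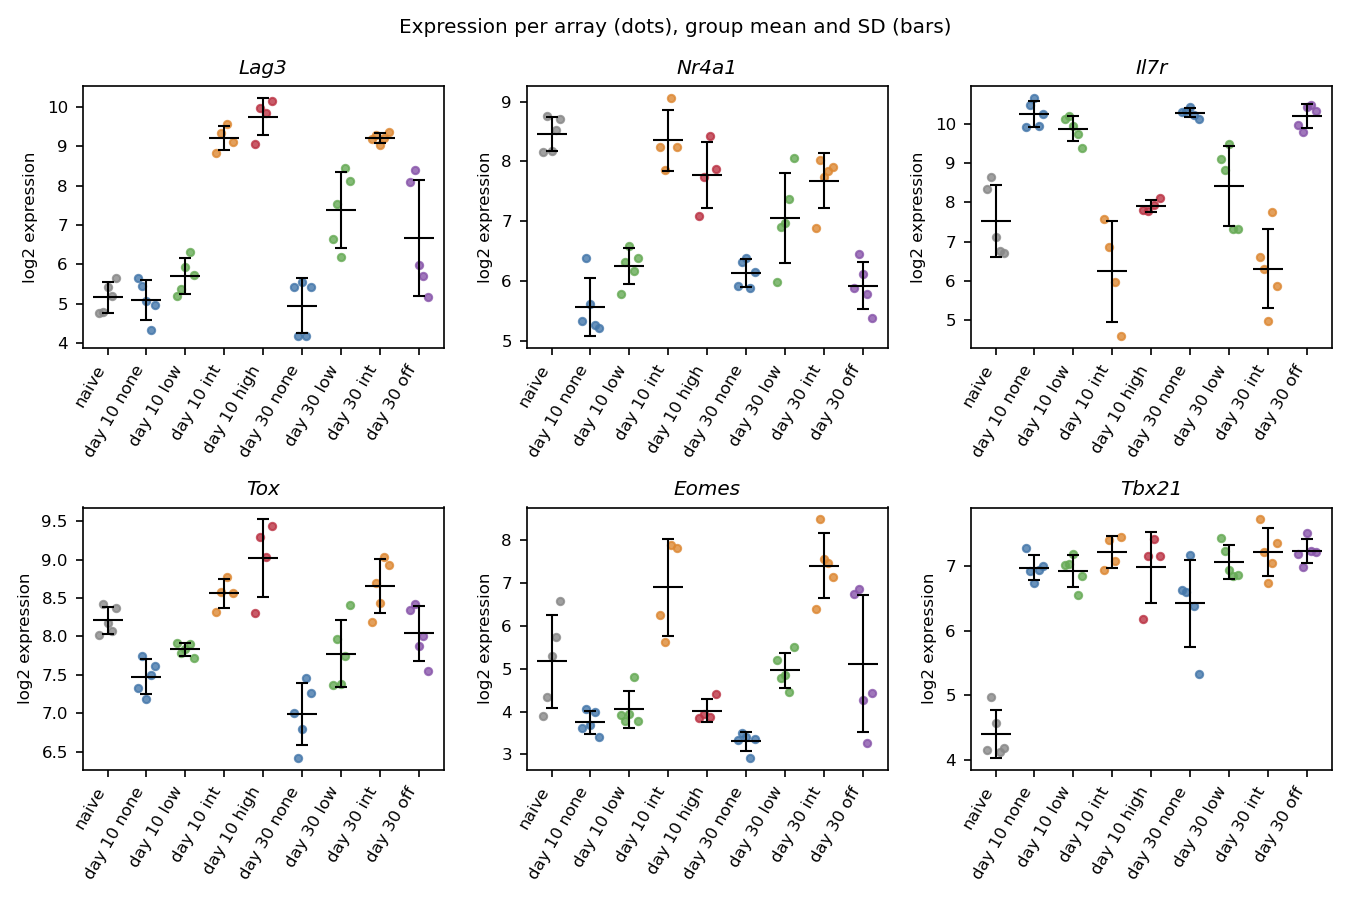
Log2 expression of 6 genes in each array (dots, coloured by treatment) with the group mean and SD (black bars) for the naive group and the 8 groups of transferred cells. Lag3 was at 9.21 and 9.22 under intermediate antigen on days 10 and 30 and at 5.09 and 4.95 without antigen, while Il7r showed the opposite order.

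High antigen in the cMCC recipients gave the broadest difference from the none group, 1165 genes on day 10, with 615 higher and 550 lower and 504 at least 2-fold. Recipient strain, the cells that present the peptide, dose, exposure to doxycycline and antigen during priming all differ between these groups, since the none group drank 100 µg/ml to day 3 and the high group had no drug at any time. The genes that rose most included Stfa3, a stefin (6.86 ± 0.43, adjusted p = 8.77e-16), the chemokine Ccl3 (6.52 ± 0.72, adjusted p = 6.67e-09) and Il21, the cytokine of follicular helper cells (5.98 ± 0.44, adjusted p = 1.33e-13). Lag3 reached 9.75 ± 0.48 (4.66 ± 0.45, adjusted p = 2.98e-10). Pdcd1 (3.14 ± 0.35, adjusted p = 8.05e-09) and Tox (1.54 ± 0.21, adjusted p = 1.36e-06) rose. Nr4a1 (2.22 ± 0.29, adjusted p = 5.64e-07), Bcl6 (1.79 ± 0.29, adjusted p = 2.27e-05) and Ifng (2.44 ± 0.36, adjusted p = 4.39e-06) were higher as well. Top2a, the topoisomerase of dividing cells, rose (2.74 ± 0.21, adjusted p = 4.97e-13), as did the glycolytic enzyme Tpi1 (1.53 ± 0.30, adjusted p = 0.000499). Il7r (-2.34 ± 0.44, adjusted p = 0.000288), the protease inhibitor Ctla2a (-4.18 ± 0.48, adjusted p = 2.17e-08) and Satb1, a chromatin organiser of T cells (-1.61 ± 0.26, adjusted p = 1.95e-05), fell.

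Of 15 exhaustion-associated transcription factors, 12 were higher and 0 lower (13 and 0 adjusted over the list alone, camera adjusted p = 2.57e-19), Bhlhe40 leading (3.26 ± 0.38, adjusted p = 2.83e-08). Inhibitory receptors rose (8 higher and 1 lower of 17, 9 and 1 adjusted over the list alone, camera adjusted p = 8.85e-11). Both TCR-induced early genes (14 higher and 0 lower of 28, 16 and 2 adjusted over the list alone, camera adjusted p = 9.53e-14) and anergy-associated genes (12 higher and 3 lower of 24, 13 and 4 adjusted over the list alone, camera adjusted p = 2.37e-11) were higher as lists. Tfh genes rose (11 higher and 0 lower of 18, 12 and 1 adjusted over the list alone, camera adjusted p = 9.47e-12), and so did Treg and Tr1 genes (10 higher and 0 lower of 20, 11 and 1 adjusted over the list alone, camera adjusted p = 9.7e-09). Egr2, on both the TCR-induced and the anergy list, rose by 1.42 ± 0.31, adjusted p = 0.00192, with 3 of 4 arrays beyond all none arrays. Cell cycle genes were higher (14 higher and 0 lower of 42, 25 and 0 adjusted over the list alone, camera adjusted p = 3.42e-13). Glycolysis and nutrient uptake genes rose (6 higher and 0 lower of 20, 9 and 1 adjusted over the list alone, camera adjusted p = 4.6e-06). Interferon-stimulated genes fell, with 6 of 28 lower and 0 higher (1 and 12 adjusted over the list alone, camera adjusted p = 7.4e-10), Oas2 (-2.0 ± 0.31, adjusted p = 1.27e-05) and Usp18 (-1.29 ± 0.24, adjusted p = 0.000287) among them. Naive and central memory genes fell as well (1 higher and 9 lower of 22, 2 and 12 adjusted over the list alone, camera adjusted p = 7.4e-10).

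The Th1 list rose under high antigen (7 higher and 3 lower of 23, 8 and 3 adjusted over the list alone, camera adjusted p = 0.00159), although Tbx21 was not called (0.01 ± 0.25, adjusted p = 0.996). Cxcr3 fell (-0.93 ± 0.20, adjusted p = 0.00208). The members that rose were led by Ccl3 and Ccl4 (3.61 ± 0.50, adjusted p = 1.11e-06), chemokines that many activated T cells make. Of 13 Th2 and Th17 genes, 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.00549), the receptors Il1r1 (0.91 ± 0.17) and Ccr6 (0.69 ± 0.16) among them. Oxidative phosphorylation genes were higher with the preset correlation (adjusted p = 0.000643) and not otherwise (adjusted p = 0.183 with an estimated correlation), with 3 of 29 members higher. Il2 and Foxp3 were not called (adjusted p = 0.989 and 0.527), and the Mki67 call (1.14 ± 0.30, adjusted p = 0.0123) ended without high replicate 2 (adjusted p = 0.0726) or 3 (0.0595). The 7 other lists, which hold the markers of other cell types, were not called (camera adjusted p 0.225 to 0.993).

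The antigen groups of day 10 were also compared with each other. Against low, intermediate antigen changed 120 genes, 68 higher and 52 lower. Tnfsf4 (4.72 ± 0.54, adjusted p = 8.05e-07), Lag3 (3.51 ± 0.45, adjusted p = 5.63e-06), and Eomes (2.85 ± 0.51, adjusted p = 0.000845) were higher in int. Nr4a1 (2.10 ± 0.29, adjusted p = 2.29e-05), Bcl6 (1.42 ± 0.29, adjusted p = 0.00519) and Ifng (2.27 ± 0.36, adjusted p = 0.000235) were higher too. Il7r (-3.63 ± 0.44, adjusted p = 2.48e-06) and Il18r1 (-2.74 ± 0.36, adjusted p = 9.08e-06) were lower. Exhaustion-associated transcription factors were higher as a list (5 higher and 0 lower of 15, 10 and 0 adjusted over the list alone, camera adjusted p = 1.41e-18). The same was found for TCR-induced early genes (5 higher and 2 lower of 28, 15 and 3 adjusted over the list alone, camera adjusted p = 9.29e-12) and for Treg and Tr1 genes (4 higher and 0 lower of 20, 8 and 0 adjusted over the list alone, camera adjusted p = 5.44e-10). Tfh genes were higher too (4 higher and 2 lower of 18, 9 and 2 adjusted over the list alone, camera adjusted p = 4.2e-08). Further lists that rose were those of anergy-associated genes (6 higher and 1 lower of 24, 10 and 4 adjusted over the list alone, camera adjusted p = 1.03e-08) and of inhibitory receptors (3 higher and 0 lower of 17, 4 and 1 adjusted over the list alone, camera adjusted p = 5.43e-05). Interferon-stimulated genes fell with 1 of 28 called, Oas2 (-1.55 ± 0.31, adjusted p = 0.00458), and 0 and 9 adjusted over the list alone (camera adjusted p = 5.2e-12). The naive and central memory list had a median of 0.05 and a mean of -0.28, and its downward call (adjusted p = 0.0113) was lost (adjusted p = 0.331 with an estimated correlation). Cell cycle genes, called higher (adjusted p = 0.0108), and oxidative phosphorylation genes, called lower (adjusted p = 0.000765), had 0 members called and lost the call too (adjusted p = 0.233 and 0.256 with an estimated correlation). Egr2 was called (1.37 ± 0.31, adjusted p = 0.0179) but not without low replicate 4 or int replicates 3 or 4 (adjusted p = 0.0763, 0.121 and 0.066); Pdcd1, Tox, Tbx21, Il2, Foxp3 and Mki67 were not called. Without int replicate 3 or 4 the count was 78 or 79.

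High against intermediate antigen called 664 genes, 311 higher and 353 lower. Stfa3 (7.05 ± 0.46, adjusted p = 4.48e-15), Il21 (2.83 ± 0.46, adjusted p = 5.41e-05), and Pdcd1 (1.84 ± 0.37, adjusted p = 0.00116) were higher under high antigen, as were Bhlhe40 (2.46 ± 0.40, adjusted p = 5.24e-05) and Top2a (1.64 ± 0.22, adjusted p = 1.61e-06). Il18r1, which intermediate antigen lowered, stood 3.70 ± 0.38 above int (adjusted p = 2.51e-09). Tnfsf4 (-4.19 ± 0.57, adjusted p = 1.52e-06), Eomes (-2.88 ± 0.53, adjusted p = 0.000378), Gzmk, a granzyme (-2.86 ± 0.43, adjusted p = 1.24e-05), and Cxcr5 (-1.65 ± 0.27, adjusted p = 6.25e-05) were lower. Cell cycle genes were higher in the high group (6 higher and 0 lower of 42, 11 and 0 adjusted over the list alone, camera adjusted p = 3.7e-06). Glycolysis genes (3 higher and 0 lower of 20, 5 and 0 adjusted over the list alone, camera adjusted p = 3.34e-06) and Th2 and Th17 genes (3 higher and 0 lower of 13, 4 and 0 adjusted over the list alone, camera adjusted p = 0.000812) were higher as well. Th1 genes, 7 higher and 1 lower of 23 (9 and 3 adjusted over the list alone), were called higher only with the preset correlation (adjusted p = 0.000619, and 0.0625 with an estimated correlation). The same held for Tfh genes (0.00775 and 0.23), inhibitory receptors (0.00764 and 0.0969), oxidative phosphorylation genes (0.000769 and 0.26) and, downwards, for naive and central memory genes (5.79e-05 and 0.0969) and interferon-stimulated genes (0.00764 and 0.365). The anergy list was not called (adjusted p = 0.0981, median -0.03, mean 0.36), nor were the TCR-induced early genes (adjusted p = 0.058). Il7r was higher in high than in int (1.66 ± 0.46, adjusted p = 0.0343), a call that ended on leaving out int replicate 3 or 4 or any single high array (adjusted p 0.0649 to 0.262) or with only these groups in the fit (0.104). Egr2, Nr4a1, Lag3, Tox, Ifng, Tbx21, Il2, Foxp3, Bcl6 and Mki67 were not called between these groups.

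Effects of different doses share the day 10 none arrays, which by itself makes them correlate. Across 22180 genes, which are not independent replicates, the fold changes of int and of high against none had a Pearson r of 0.504 (Spearman rho 0.422), where unchanged groups against the same controls gave 0.443 in simulation. The covariance was 0.0597 against a simulated 0.0203, and with the none arrays split between the comparisons r was 0.328 (0.197 to 0.419 over 20 splits). Of the calls, 102 were higher in both (4.82 for independent lists), 59 lower in both (2.53) and 4 opposite. For low and int r was 0.524 (simulated 0.472, covariance 0.0291 against 0.0204, and 0.185 with split controls), and for low and high 0.372 (simulated 0.471, covariance 0.0276 against 0.0204, and 0.133 with split controls).

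By day 30 low antigen had changed 145 genes against none, 86 higher and 59 lower, with 80 at least 2-fold; at an unadjusted p under 0.05 there were 2443. Mef2c, a transcription factor best known from muscle and B cells, rose from 3.58 ± 0.21 to 6.94 ± 0.63 (3.35 ± 0.20, adjusted p = 4.37e-16). Gucy1a1, a subunit of the nitric oxide receptor, rose by 3.55 ± 0.36, adjusted p = 2.15e-08. Lag3 (2.44 ± 0.42, adjusted p = 0.000663), Tigit (2.93 ± 0.40, adjusted p = 1.22e-05), and Il21 (2.38 ± 0.41, adjusted p = 0.000756) were higher. Ifng (1.69 ± 0.34, adjusted p = 0.00524), Irf4 (1.76 ± 0.29, adjusted p = 0.000287) and the chaperone Hspa1a (4.02 ± 0.63, adjusted p = 0.000149) rose too. Il18r1 (-2.16 ± 0.34, adjusted p = 0.000149) and Dapl1, a gene of resting T cells (-1.34 ± 0.18, adjusted p = 1.17e-05), were lower. Il7r fell (-1.87 ± 0.42, adjusted p = 0.0142), a call that ended without low replicate 4 (adjusted p = 0.0711) or 5 (0.0851) and with array quality weights (0.105). Egr2 (1.13 ± 0.29, adjusted p = 0.052) was not called with all arrays and was called without low replicate 3 (adjusted p = 0.0311) or none replicate 4 (0.0401). The same was true of Tox (0.78 ± 0.20, adjusted p = 0.052) without low replicate 1 (0.0308) or 3 (0.0299) or none replicate 4 (0.0263) or 5 (0.046). Nr4a1 (0.93 ± 0.28, adjusted p = 0.113) was called only without low replicate 1 (0.0191), and Il2 (1.27 ± 0.44, adjusted p = 0.207) without none replicate 3 (0.0123). Pdcd1, Tbx21, Foxp3, Bcl6 and Mki67 were not called.

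TCR-induced early genes rose as a list in day 30 low cells (3 higher and 0 lower of 28, 13 and 0 adjusted over the list alone, camera adjusted p = 4.98e-14). So did inhibitory receptors (3 higher and 0 lower of 17, 4 and 1 adjusted over the list alone, camera adjusted p = 4.23e-06) and exhaustion-associated transcription factors (2 higher and 0 lower of 15, 8 and 0 adjusted over the list alone, camera adjusted p = 5.94e-11). Tfh genes rose as well (3 higher and 0 lower of 18, 7 and 2 adjusted over the list alone, camera adjusted p = 4.77e-07), and so did Treg and Tr1 genes (3 higher and 0 lower of 20, 7 and 0 adjusted over the list alone, camera adjusted p = 4.55e-05). Anergy-associated genes (adjusted p = 5.98e-05, and 0.0806 with an estimated correlation), cytotoxic genes (0.00347 and 0.0806), oxidative phosphorylation genes (0.0237 and 0.434) and cell cycle genes (0.0417 and 0.33) were called higher, and naive and central memory genes (4.53e-06 and 0.0589) lower, only with the preset correlation. Th1 genes were not called as a list (4 higher, 2 lower, adjusted p = 0.118). The B cell marker Cd22 rose (2.35 ± 0.34, adjusted p = 4.93e-05) without the rest of its list (adjusted p = 0.297). The count of calls dropped to 94 without low replicate 5. With quantile normalization 97 genes were higher and 97 lower.

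Intermediate antigen kept to day 30 changed 491 genes, 315 higher and 176 lower, 216 of them by at least 2-fold. Lag3 stood at 9.22 ± 0.12 against 4.95 ± 0.71 (4.27 ± 0.42, adjusted p = 3.06e-09). Gzmk rose most (4.36 ± 0.38, adjusted p = 1.74e-10), and Tigit (4.23 ± 0.40, adjusted p = 1.03e-09) and Eomes (4.11 ± 0.48, adjusted p = 8.5e-08) were among the strongly raised genes. Il21 (3.70 ± 0.41, adjusted p = 4.27e-08), Maf (3.27 ± 0.46, adjusted p = 5.32e-06) and Ikzf2 (3.04 ± 0.38, adjusted p = 5.17e-07) rose too. Tox (1.67 ± 0.20, adjusted p = 2.37e-07), Egr2 (1.89 ± 0.29, adjusted p = 2.65e-05) and Nr4a1 (1.55 ± 0.28, adjusted p = 0.000333) were higher. So were Bcl6 (1.31 ± 0.27, adjusted p = 0.0023), Ifng (1.89 ± 0.34, adjusted p = 0.000322) and Pdcd1 (1.5 ± 0.33, adjusted p = 0.00441, 4 of 5 arrays beyond all none arrays). Il7r fell from 10.29 ± 0.12 to 6.31 ± 1.02 (-3.97 ± 0.42, adjusted p = 1.07e-08). Ly6c2 (-3.24 ± 0.46, adjusted p = 5.68e-06) and Ifngr1, a chain of the interferon gamma receptor (-2.98 ± 0.32, adjusted p = 1.3e-08), fell too. Lower as well were Cd40lg, the helper molecule CD40 ligand (-2.31 ± 0.23, adjusted p = 3.56e-09), and Dapl1 (-2.39 ± 0.18, adjusted p = 1.95e-12).

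As many as 10 of 15 exhaustion-associated transcription factors were higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 1.23e-24). The Tfh list rose (11 higher and 2 lower of 18, 12 and 2 adjusted over the list alone, camera adjusted p = 3.03e-14). The Treg and Tr1 list (8 higher and 0 lower of 20, 10 and 0 adjusted over the list alone, camera adjusted p = 4.38e-14) and the TCR-induced early list (11 higher and 1 lower of 28, 18 and 2 adjusted over the list alone, camera adjusted p = 3.03e-14) did so as well. Inhibitory receptors (5 higher and 1 lower of 17, 8 and 2 adjusted over the list alone, camera adjusted p = 1.67e-09) and anergy-associated genes (10 higher and 1 lower of 24, 10 and 3 adjusted over the list alone, camera adjusted p = 4.09e-10) also rose. Naive and central memory genes fell (1 higher and 6 lower of 22, 2 and 8 adjusted over the list alone, camera adjusted p = 7.6e-07), Satb1 with them (-1.81 ± 0.24, adjusted p = 2.17e-06). Cell cycle genes (adjusted p = 0.000665, and 0.0796 with an estimated correlation) were called higher and interferon-stimulated genes (0.0171 and 0.419) lower only with the preset correlation, with 1 member called in each. The Th1 list was not called (3 higher and 4 lower, 7 and 7 adjusted over the list alone, camera adjusted p = 0.962), nor was the cytotoxic list (0.0574, median -0.08, mean 0.47). Il2, Foxp3 and Mki67 were not called, nor was Tbx21 (0.80 ± 0.24, adjusted p = 0.0592), except without int replicate 3 (adjusted p = 0.0352) or none replicate 3 (adjusted p = 0.013). The other 9 lists were not called (camera adjusted p 0.537 to 0.986).

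**Figure D3:**
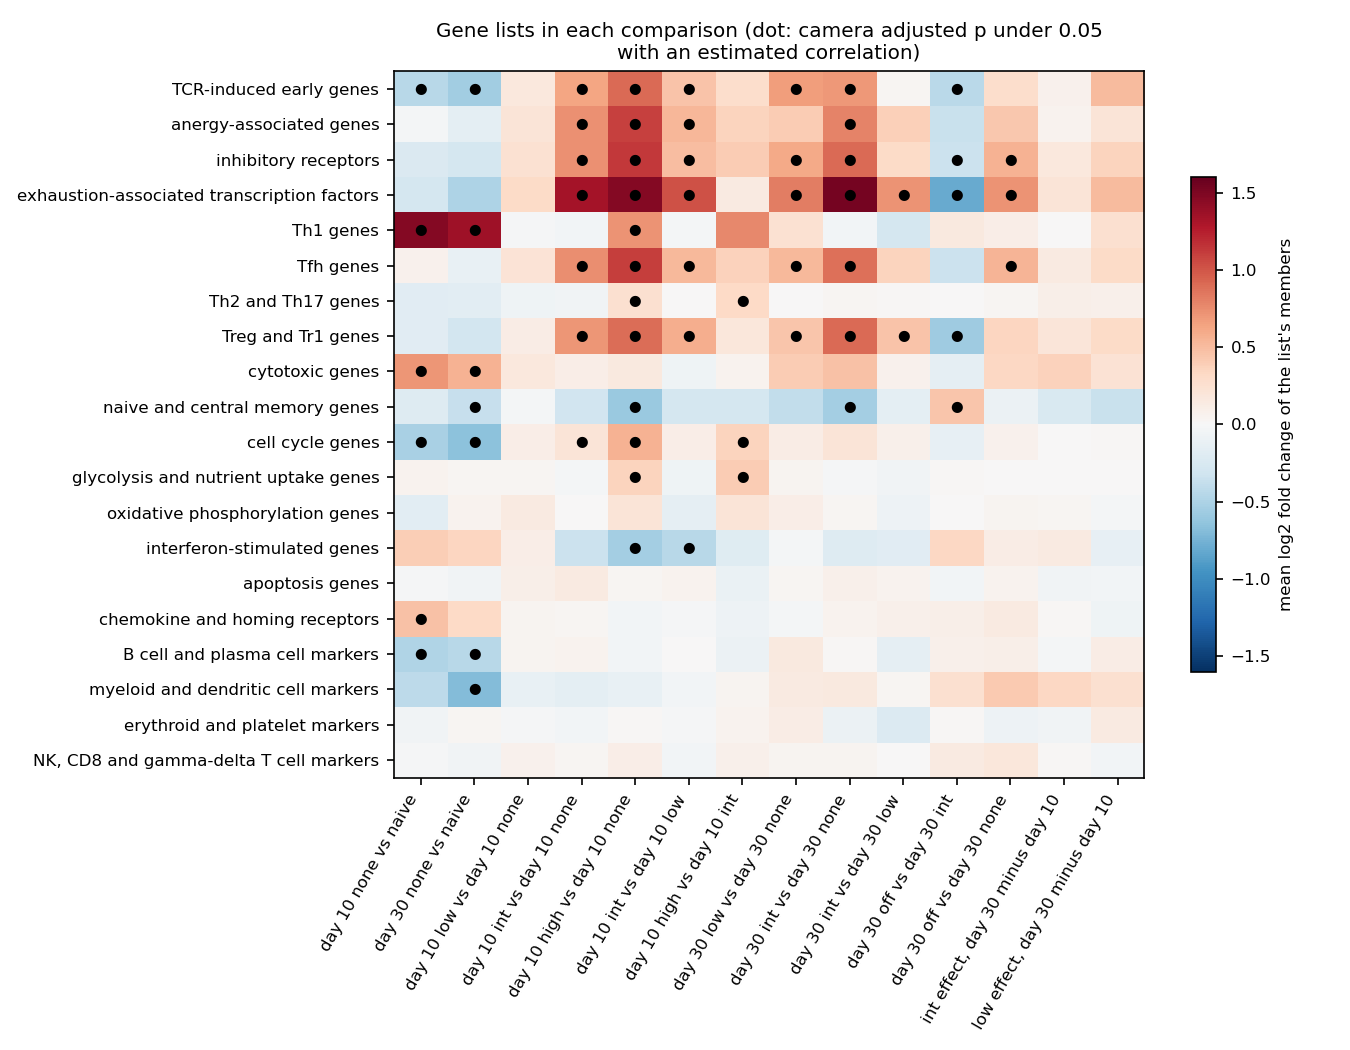
Mean log2 fold change of each of the 20 gene lists (lines of the grid) in each of the 14 comparisons (columns), from blue for lower to red for higher, with a dot where camera with an estimated correlation gave an adjusted p under 0.05. Such dots lie on 64 of the 280 squares, 7 of them in each of the 2 comparisons of intermediate antigen with none.

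Intermediate against low antigen on day 30 called 121 genes, 66 higher and 55 lower. Gzmk (2.61 ± 0.38, adjusted p = 0.000112), Eomes (2.45 ± 0.48, adjusted p = 0.00534) and Ahnak (1.74 ± 0.25, adjusted p = 0.000112) were higher in int. Mef2c (-3.30 ± 0.20, adjusted p = 7.64e-16), the lectin receptor Klrd1 (-2.55 ± 0.41, adjusted p = 0.000344), and Cd40lg (-1.61 ± 0.23, adjusted p = 9.34e-05) were lower. Il2, the T cell growth factor, was lower too (-2.33 ± 0.44, adjusted p = 0.00376), at 3.12 ± 0.31 in int and 5.45 ± 1.07 in low. Il7r was lower (-2.10 ± 0.42, adjusted p = 0.00662, 4 of 5 arrays below all low ones), a call that ended with only these groups in the fit (adjusted p = 0.118). Lag3 (1.83 ± 0.42, adjusted p = 0.0254) and Tox (0.88 ± 0.20, adjusted p = 0.0253, 4 of 5 arrays beyond) were higher. Both calls ended on leaving out low replicate 1 (adjusted p = 0.098 and 0.1), low replicate 3 (0.131 and 0.099), int replicate 2 (0.061 and 0.0604), 4 (0.0507 and 0.0961) or 5 (0.0626 and 0.0874). That of Lag3 also ended without int replicate 1 (0.0501) and that of Tox without low replicate 4 (0.0558) or with only these groups in the fit (0.149). The exhaustion-associated transcription factors (3 higher and 0 lower of 15, 6 and 0 adjusted over the list alone, camera adjusted p = 4.1e-09) and the Treg and Tr1 genes (4 higher and 0 lower of 20, 8 and 1 adjusted over the list alone, camera adjusted p = 3.74e-06) were higher as lists. Anergy-associated genes (adjusted p = 0.000442, and 0.158 with an estimated correlation), Tfh genes (0.000422 and 0.0941) and inhibitory receptors (0.0127 and 0.109), called higher, and interferon-stimulated genes (0.0475 and 0.55) and erythroid and platelet markers (0.0132 and 0.0603), called lower, lost their calls. Egr2, Nr4a1, Pdcd1, Ifng, Tbx21, Foxp3, Bcl6 and Mki67 were not called. The count of calls was 72, 67 and 78 without low replicates 1, 3 and 4 and 69 without int replicate 2.

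Against the same day 30 none arrays, the fold changes of low and int had an r of 0.627 across 22180 genes (rho 0.556), with 0.502 simulated for unchanged groups. Their covariance was 0.0542 against a simulated 0.0205, and r was 0.249 with the none arrays split (0.236 to 0.27 over 20 splits). Both comparisons called 53 genes higher (1.22 for independent lists), 36 lower (0.468) and 0 in opposite directions.

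Whether the effect of antigen differed between days was tested as an interaction. For intermediate antigen the 2 effects share no array, and across genes they had an r of 0.403 (rho 0.183, covariance 0.0377). Of the 276 genes called on day 10, 254 had the same sign on day 30. Of all calls, 113 genes were higher on both days (2.47 for independent lists), 36 lower on both (0.809) and 0 opposite. The interaction called 20 genes, 10 with a higher and 10 with a lower signed value on day 30. The effect on Hspa1a differed most (5.29 ± 0.92, adjusted p = 0.00484), being -3.10 ± 0.67 on day 10. Among the other called genes were Kcnma1, a potassium channel (1.72 ± 0.29, adjusted p = 0.00475), and Dapl1 (-1.46 ± 0.26, adjusted p = 0.00484). The call of Kcnma1 ended with the mean of its probe sets (adjusted p = 0.0538). The effects on Lag3 (0.15 ± 0.61, adjusted p = 0.99), Il7r (0.03 ± 0.61, adjusted p = 0.997), Egr2 (0.06 ± 0.42, adjusted p = 0.994), Tox (0.58 ± 0.29, adjusted p = 0.75) and Nr4a1 (-1.24 ± 0.41, adjusted p = 0.464) were not called as different between days. camera called 0 of the 20 lists, while limma gave 1486 genes an unadjusted p under 0.05.

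For low antigen the interaction called 7 genes, 4 with a higher signed effect on day 30, led by Mef2c (3.57 ± 0.28, adjusted p = 1.13e-11) and Gucy1a1 (3.10 ± 0.52, adjusted p = 0.00194). In 3 the signed effect was lower, among them Atp1b1, a subunit of the sodium pump (-2.01 ± 0.34, adjusted p = 0.00219), and Dapl1 (-1.55 ± 0.26, adjusted p = 0.00194). The low effects of the days had an r of 0.162 across genes (rho 0.118). TCR-induced early genes (adjusted p = 4.98e-06, and 0.0927 with an estimated correlation), exhaustion-associated transcription factors (0.00384 and 0.298), Treg and Tr1 genes (0.018 and 0.298) and Tfh genes (0.0182 and 0.298) had a higher signed effect on day 30 and naive and central memory genes (0.000208 and 0.298) a lower one only with the preset correlation. Lag3 (1.82 ± 0.59, adjusted p = 0.637), Ifng (1.74 ± 0.48, adjusted p = 0.337) and Il7r (-1.50 ± 0.59, adjusted p = 0.797) were not called as different. Each of them was called in low against none on day 30 and not on day 10, which therefore does not show that the days differ.

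**Figure D4:**
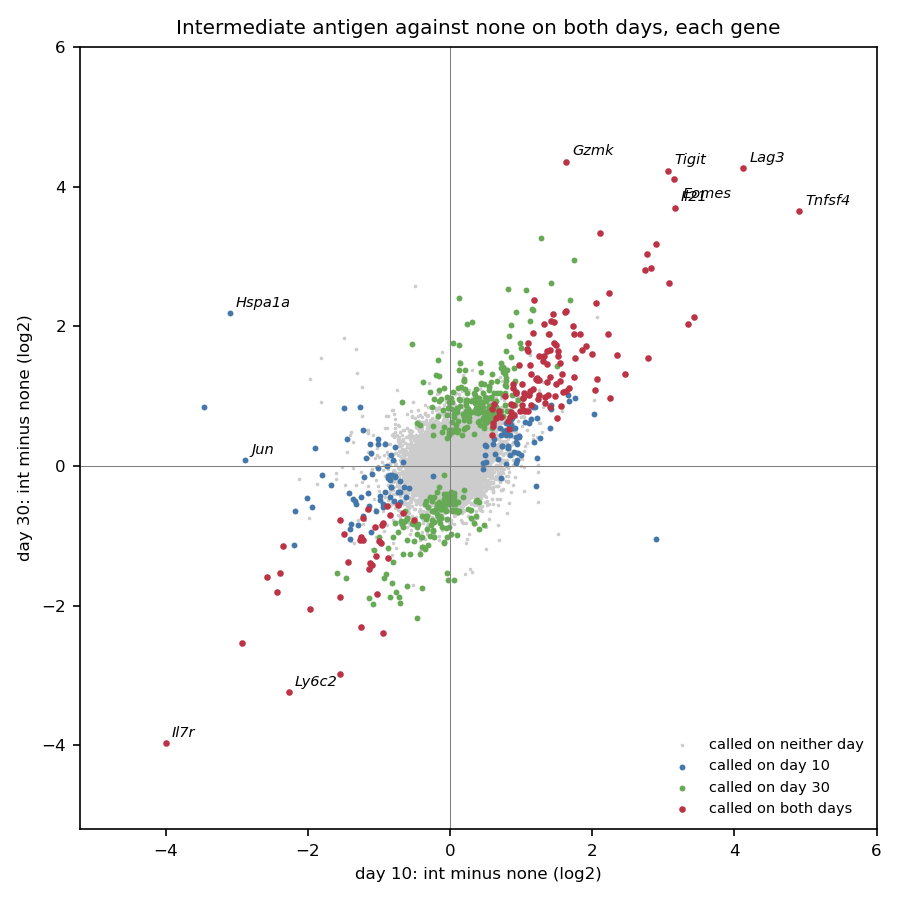
Log2 fold change of intermediate antigen against none for each of 22180 genes on day 10 (horizontal) and on day 30 (vertical), coloured by the day on which the gene was called. The 149 genes called on both days lie to the upper right (113) and the lower left (36), and Hspa1a, called on day 10 only, lies at -3.10 there.

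The off group asks how far the state under intermediate antigen returns once doxycycline, which sets the antigen, is removed on day 10. Against int on day 30, limma called 103 genes, 59 higher and 44 lower in off. Il7r stood at 10.20 ± 0.30 in off against 6.31 ± 1.02 in int (3.89 ± 0.42, adjusted p = 1.38e-07). Ly6c2 (2.94 ± 0.46, adjusted p = 0.000188), Cd40lg (1.91 ± 0.23, adjusted p = 1.03e-06) and Dapl1 (1.64 ± 0.18, adjusted p = 1.75e-07) were higher as well. Klk1b27, a kallikrein (-3.93 ± 0.47, adjusted p = 1.02e-06), Tnfsf4 (-3.28 ± 0.51, adjusted p = 0.000178), and Gzmk (-2.87 ± 0.38, adjusted p = 1.09e-05) were lower, and Irf4 (-2.03 ± 0.29, adjusted p = 3.79e-05), Nr4a1 (-1.75 ± 0.28, adjusted p = 0.000241) and Ctla4 (-1.34 ± 0.23, adjusted p = 0.000547) fell with them. Lag3 was lower too (-2.55 ± 0.42, adjusted p = 0.000419), a call that ended with only these groups in the fit (adjusted p = 0.052). Egr2 was lower (-1.33 ± 0.29, adjusted p = 0.0153), a call that ended without int replicate 2 (0.0544) or off replicate 4 (0.0854) or 5 (0.114) or with only these groups in the fit (0.163). Exhaustion-associated transcription factors fell (0 higher and 3 lower of 15, 0 and 8 adjusted over the list alone, camera adjusted p = 3.08e-13). Lists that fell with them were the Treg and Tr1 genes (0 higher and 4 lower of 20, 0 and 7 adjusted over the list alone, camera adjusted p = 1.58e-10) and the TCR-induced early genes (1 higher and 5 lower of 28, 1 and 12 adjusted over the list alone, camera adjusted p = 4.36e-08). Inhibitory receptors fell too (1 higher and 3 lower of 17, 3 and 4 adjusted over the list alone, camera adjusted p = 0.00117). Rising instead were naive and central memory genes (4 higher and 0 lower of 22, 7 and 1 adjusted over the list alone, camera adjusted p = 3e-07). With the preset correlation alone, anergy-associated genes (adjusted p = 0.000315, and 0.121 with an estimated correlation), Tfh genes (0.000505 and 0.0769) and cell cycle genes (0.0256 and 0.287) were lower and interferon-stimulated genes (6.48e-07 and 0.0562) and myeloid markers (0.0327 and 0.299) higher. Pdcd1, Tox, Ifng, Tbx21, Bcl6, Il2, Foxp3 and Mki67 were not called. The count was 66 without off replicate 4 and 53 without off replicate 5.

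Against none, the off group differed in 59 genes, 43 higher and 16 lower (2470 at unadjusted p under 0.05). Of the 59, int called 33 alike and 1 in the other direction. S100a8, a myeloid marker, rose most (3.44 ± 0.79, adjusted p = 0.0365). Like it, S100a9 (2.87 ± 0.67, 0.0458) and Hspa1a (2.87 ± 0.63, 0.024) rose with no int call. Of the 10 arrays left out in turn, 7, 9 and 6 ended these 3 off calls, as did array quality weights (0.11, 0.134 and 0.0555). Without a variance trend those of S100a8 and S100a9 ended (0.0527 and 0.0616), and with quantile normalization that of S100a9 (0.0541). Kcnma1 (1.97 ± 0.20, adjusted p = 2.7e-08), the adaptor Plekho1 (2.09 ± 0.26, adjusted p = 5.21e-06) and Hmox1, which encodes heme oxygenase 1 (2.13 ± 0.28, adjusted p = 1.34e-05), were higher. The tetraspanin Cd81 (2.08 ± 0.31, adjusted p = 0.000115) and Rgs1, a brake on chemokine signalling (1.67 ± 0.30, adjusted p = 0.00267), rose and Sytl2 (-1.73 ± 0.24, adjusted p = 2.85e-05) fell. Maf (2.39 ± 0.46, adjusted p = 0.00737), Tigit (2.34 ± 0.40, adjusted p = 0.00158) and Tox (1.05 ± 0.20, adjusted p = 0.00747) were higher as well. These 3 calls ended with only these groups in the fit (adjusted p = 0.0584, 0.128 and 0.138). Lag3 was not called (1.72 ± 0.42, adjusted p = 0.0592), except without off replicate 3 (adjusted p = 0.048), 4 (0.0279) or 5 (0.0108), and Tbx21 (0.81 ± 0.24, adjusted p = 0.146) only without none replicate 3 (0.0497). Egr2, Nr4a1 (-0.21 ± 0.28, adjusted p = 0.838), Pdcd1, Il7r (-0.08 ± 0.42, adjusted p = 0.965), Ifng, Il2, Foxp3, Bcl6 and Mki67 were not called. Inhibitory receptors stayed above none as a list (1 higher and 0 lower of 17, 5 and 0 adjusted over the list alone, camera adjusted p = 1.96e-05). This was also true of Tfh genes (1 higher and 0 lower of 18, 7 and 0 adjusted over the list alone, camera adjusted p = 3.51e-08) and exhaustion-associated transcription factors (3 higher and 0 lower of 15, 7 and 0 adjusted over the list alone, camera adjusted p = 9.49e-08). Anergy-associated genes (adjusted p = 1.67e-05, and 0.0932 with an estimated correlation), TCR-induced early genes (0.000519 and 0.104), Treg and Tr1 genes (0.00628 and 0.118), cytotoxic genes (0.0125 and 0.14), chemokine and homing receptors (0.0345 and 0.104) and myeloid markers (0.00628 and 0.175) were higher only with the preset correlation. Of the myeloid markers 3 of 25 were called, S100a8, S100a9 and C1qb. The count was 24 without off replicate 1 and 29 without off replicate 2.

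Over the 491 genes that intermediate antigen changed on day 30, the off group kept a share of 0.41 of the change. This slope ran from 0.39 to 0.427 over 20 divisions of the none arrays and from 0.349 to 0.447 on leaving out single arrays. Of these genes, 73 were also called between off and int, and 387 were called neither there nor between off and none. Directions are not read from these counts and the share may be biased, as these int and none arrays chose the genes. The off arrays were spread widely along the line from none (0) to int (1), replicates 1 to 5 standing at 0.593, 0.652, 0.268, 0.261 and 0.275. Int arrays lay at 0.89 to 1.011, low arrays at 0.357 to 0.627 and none arrays at -0.014 to 0.04, each int and none array being placed against the other arrays of its group. Lag3 in off replicates 1 to 5 was at 8.09, 8.39, 5.98, 5.7 and 5.16 and Eomes at 6.75, 6.86, 4.27, 3.27 and 4.43, whereas Il7r was at 9.98, 9.8, 10.42, 10.49 and 10.33. The off mean therefore stands for differing arrays.

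**Figure D5:**
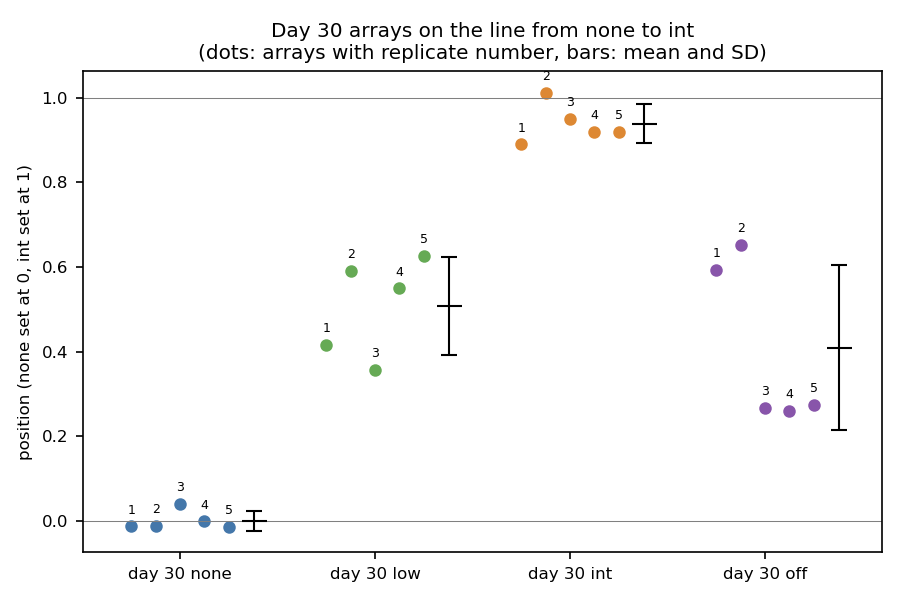
Position of each day 30 array on the line from the none group (0) to the int group (1) over the 491 genes called between them, with replicate numbers and the mean and SD of each group beside the dots. The off arrays lie between 0.261 and 0.652, wider apart than the arrays of the int group at 0.89 to 1.011.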

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

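The 14 counts of other divisions below come from tests written before the results were seen, and the 9 tests that weigh explanations were all chosen only afterwards. Each comparison was repeated after regrouping its arrays, and the number of divisions that called at least as many genes as the real one, itself included, was counted. It was 1 of 100 splits for low (1 gene called, highest other split 0), int (276, highest other 139) and high against none (1165, 895) and int against low (120, 33) on day 10, 1 of 35 splits for high against int (664, 26), and 1 of 100 splits for day 30 none against naive (961, 104), low (145, 16) and int against none (491, 55), int against low (121, 13), off against int (103, 15), off against none (59, 9) and the interaction of low antigen with day (7, 3). For day 10 none against naive it was 2 of 100 splits (733), and the highest other split, which exchanged none replicate 4 with naive replicate 2, gave 795. For the interaction of int with day it was 5 of 100 splits (20), so a grouping by chance is not excluded for that count. The highest other split there gave 453; it exchanged all labels on day 30 and a pair of labels on day 10, which adds the effects of both days instead of subtracting them.

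Among 26 genes and positions, some of them chosen after their values were seen, 238 groups were searched for an array far from the rest, by a gap to the nearest array that is large for the range of the group. Such an array was found in 17 groups, where about 1 in 20, or 11.9, are found by chance. Day 10 high replicate 2 stood low for Egr2 (6.17, nearest array 7.73), Cd4 (9.1, nearest 10.26), Cd3e (11.01, nearest 11.56), Ptprc (10.62, nearest 11.03) and Kcnma1 (11.32, nearest 12.49). In other groups Nr4a1 stood apart in day 30 int replicate 1 (6.89), Ifng in day 10 high replicate 5 (5.77) and none replicate 2 (5.65), Il2 in day 10 int replicate 3 (3.21), Foxp3 in naive replicate 3 (6.42), Mki67 in day 30 int replicate 3 (5.07), Thy1 in day 10 low replicate 4 (10.77), Mef2c in day 10 high replicate 4 (3.84) and day 30 int replicate 5 (4.32), Hspa1a in day 30 int replicate 4 (2.54) and Cd79a in day 30 low replicate 3 (4.09). On the line from none to int, day 30 none replicate 3 stood at 0.04, apart from the other none arrays.

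The effect of int antigen differed between days by the interaction test for 15 genes that carry a name allowed by the rule. The signed effect was higher on day 30 for Hspa1a (5.29, adjusted p = 0.00484), Gzmk (2.73, 0.0222), Fos (2.33, 0.0241), Rabif (2.12, 0.00543), Gabbr1 (1.82, 0.0097), Kcnma1 (1.72, 0.00475), Nlrc3 (1.44, 0.0251) and Piezo1 (1.22, 0.0413), and lower, which for a gene that antigen lowers is a deeper fall, for Smc4 (-0.75), Rgs10 (-1.03), Il6st (-1.07), Olfr503 (-1.31) and Dapl1 (-1.46), each at an adjusted p of 0.00484, Spg20 (-1.32, 0.00813) and Atp1b1 (-1.68, 0.0241). For low antigen the difference was 3.57 for Mef2c (adjusted p = 1.13e-11), 3.10 for Gucy1a1 (0.00194), 2.09 for Nt5e (0.0316), 1.71 for Kcnma1 (0.00194), -1.55 for Dapl1 (0.00194), -1.72 for Sytl2 (0.0236) and -2.01 for Atp1b1 (0.00219). On leaving out single arrays the int call of Gzmk ended without day 10 int replicates 1 and 2 (0.11 and 0.115), day 10 none 4 (0.0608), day 30 int 3 (0.0556) and day 30 none 5 (0.0563). Calls for int that ended without any 1 of several arrays were those of Fos (9 arrays, adjusted p up to 0.0842), Nlrc3 (9, up to 0.0967), Piezo1 (10, up to 0.163) and Atp1b1 (8, up to 0.11), and for low those of Nt5e (12, up to 0.103) and Sytl2 (8, up to 0.0953). With only the compared groups in the fit the int calls of Smc4 and Spg20 (0.0866) and Rgs10 (0.0664) ended, and with the mean of its probe sets the low call of Kcnma1 (0.0585).

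B cell and myeloid markers stood high in naive replicates 3 and 4, so sample purity could make transferred cells differ from naive cells. Without these arrays, called genes outside the marker lists kept a median 0.918 of their fold change between day 10 none and naive (quartiles 0.796 to 1.033, 727 genes). This argues against RNA particular to replicates 3 and 4 as the source of most of the difference. The 6 called marker genes kept 0.396, as such RNA could produce. Such RNA in the other naive arrays was not tested, and their Cd79a levels also lay above the means of all other groups (3.24 to 3.70). The CD45.1 sort should exclude other T cells, but any left in naive samples could also supply Foxp3 and Ikzf2. Without these arrays they were at -1.26 (adjusted p = 0.00424) and -3.22 (4.49e-06). The receptor segment Trav14d-3-dv8 was lower in none than in naive (-1.96, adjusted p = 0.000992) and Trbv13-2 was not called (-1.20, 0.152), but both lie near the floor and were picked after 6 segments had been seen, so this explanation stays open.

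The off arrays 1 and 2 stood nearer to int than the other off arrays did, at 0.593 and 0.652 against 0.268, 0.261 and 0.275. An exchange of labels with int is unlikely, since the lowest int array stood at 0.89, and so is an exchange with low, since no off array passed 0.16 on 8 genes particular to low, where the lowest low array stood at 0.87. A mixture of cells like int and cells like none within these samples would give the same share of int from genes that int raises and lowers, and the shares were 0.57 and 0.56 in replicate 1 and 0.70 and 0.69 in replicate 2, a difference of 0.01 at most, judged against a bound of 0.1 set after the shares were seen. Single genes go against a plain mixture. Il7r stood at 9.98 and 9.8, at least 0.46 above the highest level that these shares allow (9.52 and 9.17), and Xcl1 at 9.92 and 10.12, above every int and none array (8 at most). Over all genes, 2 lay at least 1 log2 unit beyond all int and none arrays in both off arrays, while pairs of int or none arrays gave up to 5 such genes, so a mixture is not excluded. Contact with antigen that continued after the drug was removed would keep TCR-induced early genes up, and on 12 such genes these arrays stood at 0.501 and 0.65, the other off arrays at 0.128, 0.037 and -0.063 and the highest none array at 0.149. The remaining genes of the 491 stood at 0.597 and 0.652 in these arrays, and a mixture would raise the early genes as well. This test therefore cannot tell continued contact from a mixture. Nr4a1, itself an early gene, stood at 5.92 ± 0.40 (SD) over all off arrays, 6.13 ± 0.23 in none and 7.68 ± 0.45 in int. Both explanations stay open. Il7r and Xcl1, which go against a mixture, and Nr4a1 and Egr2 were picked here after their values were seen.

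Hspa1a, Hspa1b, Jun and Fos were lower with int on day 10 and not called with int on day 30, while Hspa1a and Hspa1b were higher with low on day 30. The int effect on Hspa1a was 5.29 higher on day 30 (adjusted p = 0.00484) but not called then (0.0518), so effects in 1 direction stay open. Stress of single samples between sort and lysis could raise these genes together, and within groups Hspa1a correlated with Jun, Fos and Dusp1 at a mean Pearson r of 0.515 over 43 arrays (Spearman rho 0.388; one-sided permutation p = 0.00029 and 0.00062), or 0.416 without the 2 arrays farthest from the median. Those 3 partners were picked after the values were seen. Of the other genes examined Hspa1b correlated most, at 0.762 (rho 0.683), and Fosb stood at 0.369. The other heat shock genes correlated less, with Dnajb1 at 0.267, Hsp90aa1 at 0.241, Hspe1 at 0.068, Hsph1 at -0.052, Hspd1 at -0.075 and Hspa8 at -0.305. Handling therefore stays a candidate explanation beside a joint induction by antigen that depends on the day.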

How the results depend on the processing

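The tests named here were fixed before the results were seen, except those without 4 arrays and those with single off arrays, which were chosen only afterwards. Of the fold changes of named genes under the other settings, 22964 kept their direction and their side of the threshold, 792 lost the call, 239 gained it and 0 reversed. With an estimated correlation 59 of the 123 list calls were lost. No comparison moved its share of higher calls by over 10 percentage points under quantile normalization or centring. Dim genes lie near the background of the arrays, which limits what can be called among them.

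With array quality weights limma called 13 genes for low against none, 581 for int against none and 354 for int against low on day 10, 71 for low against none, 75 for int against low and 19 for off against none on day 30, and 13 in the low interaction. With only the compared groups in the fit, and so fewer arrays to estimate the spread, it called 438 for day 30 none against naive, 2 for low against none, 208 for int against low and 345 for high against int on day 10, 74 for low against none, 292 for int against none, 45 for int against low, 35 for off against int and 18 for off against none on day 30, and 10 and 16 in the int and low interactions. The low interaction gave 12 with the filter on dim genes. Low against none on day 10 gave 0 with quantile normalization, with centring, without a variance trend and without 4 arrays, and day 10 none against naive gave 384 without those 4 arrays. The day 10 agreement of int and high was 0.328 with the none arrays divided, which removes the shared controls, and the share left in the off group was 0.593, 0.652, 0.268, 0.261 and 0.275 in off replicates 1 to 5 taken alone. Except where the construction of the setting shows it, the cause was not tested.

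Leaving out single arrays gave 492 to 917 calls for day 10 none against naive, 768 to 917 for day 30 none against naive, 0 to 1 for low, 170 to 270 for int and 803 to 1403 for high against none on day 10, 78 to 102 for int against low and 458 to 922 for high against int on day 10, 94 to 169 for low and 376 to 512 for int against none, 67 to 110 for int against low, 53 to 128 for off against int and 24 to 66 for off against none on day 30, 14 to 25 and 5 to 10 in the int and low interactions, and a share of 0.349 to 0.447 left in the off group.

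Replicate numbers did not pair the arrays: over 164 pairs of arrays with the same number the deviations from the group means had a mean correlation of 0.002 (-0.186 to 0.203), 7 pairs were over 0.1, and 9 of 43 arrays correlated best with their own number. With the replicate number as a block, the counts were 725 and 914 for none against naive on days 10 and 30, 1, 258 and 1091 for low, int and high against none, 112 for int against low and 614 for high against int on day 10, 127 and 486 for low and int against none, 108 for int against low, 107 for off against int and 60 for off against none on day 30, and 25 and 9 in the int and low interactions.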

Other observations

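Mef2c set the day 30 low group apart from every other group. Mef2c stood at 6.94 ± 0.63 (SD, n = 5) there and at group means of 3.38 to 3.63 elsewhere, the int group of the same day included. Gucy1a1 was not called between low and int on day 30 (adjusted p = 0.075). It stood at 6.86 ± 1.33 (SD, n = 5) in day 30 low, 5.48 ± 0.54 (SD, n = 5) in day 30 int and 3.3 ± 0.42 (SD, n = 5) in day 30 none. Kcnma1, a potassium channel gene, was lowest in day 30 none cells, at 10.39 ± 0.42 (SD, n = 5), against means of 12.15 to 12.55 in the other transferred groups and 11.58 ± 0.34 (SD, n = 5) in naive cells.

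Klk1b27, a kallikrein gene, stood at 7.27 ± 1.01 (SD, n = 5) in day 30 int, 5.57 ± 1.02 (SD, n = 5) in day 30 low, 5.41 ± 1.25 (SD, n = 5) in day 30 none and 3.34 ± 0.74 (SD, n = 5) in day 30 off, with means of 2.80 to 3.63 on day 10. S100a8, a gene of neutrophils and monocytes, was at 7.90, 7.34 and 8.49 in off replicates 3 to 5 and at 8.16, 8.27 and 7.57 in day 10 none replicates 3 to 5, and S100a9 was at 7.07, 6.80 and 8.04 and at 7.74, 7.97 and 7.35 in the same arrays. Xcl1, a chemokine, was at 9.92 and 10.12 in off replicates 1 and 2, above the int arrays of the same day at 6.30 to 8.00. These genes were chosen after their values were seen.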
